A study of Mus musculus with 18 samples.

How the data were processed

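Transcript levels in mouse heart were measured on Clariom S mouse arrays in 18 samples: 4 normoxic and 5 hypoxic samples at P8 (numbers 13, 22, 23 and 24, and 4 to 8) and 4 normoxic and 5 hypoxic samples at P30 (numbers 2 to 5, and 1 to 5). Groups and numbers come from the sample labels. Per the labels' protocols, RNA was isolated with a column kit for fibrous tissue, labelled with biotin by a whole-transcript kit, and only samples above a set RNA integrity were hybridised. The deposited value table holds log2 signals per transcript cluster, normalized by the authors with a method that is not given in the sources used here, and the submitters' processing notes name Affymetrix Expression Console without a version. Its scale was taken from the values, whose SD per group equals that in the gene lists. Each array's median was 7.38 to 8.07. The table used here holds 4704 probes, all of which differ between the 4 groups, by a rule not given in the sources used here. The authors' deposited gene lists for P8 and P30 give group averages as log2 signal, a signed fold change (a score of at least 1 in size, negative where hypoxia is lower), and a p-value and q-value from a test not given in the sources used here. Per the file headers these compare hypoxia with normoxia at 1 age. The averages differ from the arithmetic means of the samples by up to 1.97 at P8, so the authors' folds are printed as theirs only. The deposited enrichment tables give a p-value, a q-value and an enrichment ratio per Gene Ontology term from a background of 8815 genes, with comparison and tool not given in the sources used here. The gene column of these tables was shifted in part and was not used. In the gene lists, 5 symbols at P8 and 3 at P30 had been turned into dates and were left unnamed, and 3 p-values turned into clock times were converted back.

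A probe was named only where a gene list pairs it with symbols: 2568 probes have 1 symbol, 105 have several, from which no gene was named, and 2031 have none here. Of the symbols, 89 were updated through a RefSeq gene table of assembly GRCm38.p6. For lists, the probe with the highest mean stood for a gene. No control probe was in the table. Identical values in 34 probes were kept as they are.

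All comparisons were fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit, eBayes) on the deposited log2 values, over all 4 groups without a block, with 14 residual and 5.98 prior degrees of freedom. They were hypoxia against normoxia at each age, the difference between these effects, and P30 against P8 in each oxygen group. Because the probes in the table had been selected for differing, Benjamini-Hochberg adjustment used 22201 tests, the array's number as worked out from the q-values, p-values and ranks in the gene lists. This choice was made after the table and both counts had been seen, and adjusting over the table alone is given as an alternative. The threshold was an adjusted p of 0.05. On simulated data in which a table was selected in this way, 9.23% of the calls at P8 and 5.83% at P30 were of unchanged probes, against 30% and 22.4% when adjusted over the selected table alone. P-values of the lists compare them with other selected probes, not with all genes.

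Before the data were examined, 24 gene lists were fixed: fetal isoforms, imprinted growth genes, adult cardiomyocyte genes, cardiac ion channels, calcium handling, adrenergic and muscarinic signalling, fatty acid oxidation, oxidative phosphorylation and TCA cycle, glycolysis, HIF targets, cell cycle, extracellular matrix, stress and immediate early genes, and markers of endothelial, fibroblast and mural, erythroid, macrophage, neutrophil, lymphocyte, atrial, skeletal muscle, adipose, lung and Schwann cells. Lists of at least 3 measured genes were tested with camera at its preset correlation of 0.01 and with an estimated one, adjusted over 17 lists. Limma's fry, planned beside camera, tests whether a list moves by itself, not against other probes. Members selected for differing favour its calls. It is given for hypoxia at each age only where it departs from camera with the preset correlation. Exact binomial tests set each list's share in the authors' deposited gene lists against the share of the array listed, adjusted over the fixed and added lists of each age. They treat the genes of a list as independent, so p-values are too low where genes move together. They also set genes against a share of probes. Lists of interferon-induced and amino acid response genes were added after the values had been seen. Genes were named by a rule also fixed before the data were examined: among probes with 1 symbol, past the threshold and with groups that do not overlap, the 6 largest rises and falls in hypoxia at each age. The rule adds the 3 members with the largest statistic of each list with 3 or more called, otherwise 1, the 6 largest statistics of the difference in effect, the 5 largest rises and falls with age, a few check genes (Nppb, Myh7, Tnni1 and Slc2a1 had values), and the 5 largest rises and falls and the leading terms of the authors' deposited tables. Wsb2, as the single probe with a q-value under the threshold, Nppb beside the P30 list, the amino acid response genes and sample medians of lists were chosen after their values were seen. A few genes that the rule names, and 1 list, are not reported here.

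Relations with age were set beside 100 simulated data sets of unchanged groups that share the same control samples, and beside splits of those samples. Shares of the age probes that are higher in hypoxia were computed but not used, since those probes were chosen on the same normoxic samples. Alternatives tried were quantile normalization, centring each array on its median, leaving out probes with a mean under the 30th percentile (log2 6.03), 1 probe per gene, a trended and robust prior, array weights, fitting only the groups compared, fold thresholds of 1.5 and 2, the sample number as a block, an estimated correlation and leaving out each sample. Quantile normalization and centring used the selected probes alone, so equal sample medians over them follow by construction. Added after seeing the data were the adjustment over the table alone, leaving out hypoxic P8 samples 4 and 5, and marker means as covariates. The labels give no sex, litter, batch or scan date, so none could be examined.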

Results

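The series compares the hearts of mice kept in normal air with those of mice in hypoxia at 11% oxygen, at postnatal day 8 (P8) and day 30 (P30). Its title names delayed maturation of the heart in a model of congenital heart disease with low blood oxygen, which is the question these comparisons address. RNA was hybridised to Clariom S arrays, on which a probe set, called a probe here, stands for 1 transcript cluster. There were 4 normoxic and 5 hypoxic samples at P8 and 4 normoxic and 5 hypoxic samples at P30. The labels do not say that each sample is a separate animal, so p-values measure the spread between these samples. Nor do the labels say whether P30 mice stayed in hypoxia throughout. Values per sample were used for 21.2% of the 22201 probes tested on the array. These probes are a selection: in each of them the highest and lowest of the 4 group means lay at least 0.46 apart on the log2 scale. They name 2562 genes, all through the authors' gene lists of probes with an unadjusted p of up to 0.05 for hypoxia against normoxia. This selection favours passing when adjusted over a list alone, so those counts are not separate support. The number of arrays limits the precision of every value below. The first principal component, with 59.1% of the variance, placed all P8 samples below 0 (-69.5 to -16.7) and all P30 samples above 0 (up to 51.5). The 5 hypoxic P8 samples (-69.5 to -55.1) lay apart from the 4 normoxic ones (-34.6 to -16.7). All probes used for this component differ between the 4 groups by selection, which by itself favours such a separation.

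At P8, hypoxic hearts had higher transcript levels of genes for glucose uptake and glycolysis than normoxic hearts. Slc2a1, the glucose transporter GLUT1, rose 7.49-fold, from 8.55 ± 0.23 (SD, n = 4) to 11.46 ± 0.33 (SD, n = 5) on the log2 scale, with a limma adjusted p of 1.75e-06. Pfkp, a phosphofructokinase, rose 8.85-fold and Slc16a3, the lactate exporter MCT4, rose 9.31-fold. In all 3 genes every hypoxic sample lay above every normoxic one. Of 13 glycolysis genes with values, 12 rose over all genes tested and 13 when adjusted over the list alone, with a median log2 difference of 1.61. Among 11 targets of the hypoxia-inducible factor HIF, 7 rose and 10 did so adjusted over the list alone (median 1.34). They included Ndrg1 at 2.55 ± 0.33 (SE), the mitophagy receptor Bnip3 at 2.24 ± 0.30 and Angptl4, an inhibitor of lipoprotein lipase, at 2.12 ± 0.33. By limma's camera with its preset correlation, both lists stood above the other probes (adjusted p = 1.86e-05 for glycolysis and 0.0275 for HIF targets). Neither call held with an estimated correlation (adjusted p = 0.108 for each, the highest over their alternatives, which began at 2.45e-06 and 0.00999). The HIF call also ended without hypoxic samples 4 and 5 (adjusted p = 0.0558).

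Genes of the mitochondrion went both ways at P8. Of 13 fatty acid oxidation genes, 6 rose, among them Cpt1b, which carries long-chain fatty acids into the mitochondrion (log2 difference 1.38 ± 0.25, SE), the acyl-CoA thioesterase Acot2 (3.13 ± 0.57) and the acyl-CoA synthetase Acsl1 (1.23 ± 0.27). Adjusted over the list alone, 9 of them rose and 2 fell, and camera did not set the list apart (adjusted p = 0.212). Limma's fry called the list higher (adjusted p = 5.67e-04). Of 8 oxidative phosphorylation and TCA cycle genes, 2 fell and 1 rose, or 6 and 1 adjusted over the list alone, with a median of -0.79. Fumarase, Fh1, was lower by a log2 difference of -1.26 ± 0.27 (SE) and Ndufa4, a subunit of the respiratory chain, by -0.89 ± 0.19, whereas malate dehydrogenase 2, Mdh2, was higher by 1.30 ± 0.37. Camera placed this list below the other probes (adjusted p = 0.0219, and 0.396 with an estimated correlation, the highest over alternatives that began at 0.00682). The call of Acsl1 ended with arrays centred on their medians (adjusted p = 0.0620, over alternatives of 0.00180 to 0.0801), and that of Ndufa4 with only the 2 groups compared in the fit (0.0685, over alternatives of 0.00105 to 0.0685). That of Mdh2 ended without normoxic samples 13, 22 or 24 or hypoxic samples 6, 7 or 8 (log2 difference 1.05 to 1.59 over samples left out, adjusted p over alternatives 0.00104 to 0.206).

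Genes of dividing cells were higher in hypoxia at P8. All 33 cell cycle genes with values were higher, 21 passed the test over all genes tested and 33 passed adjusted over the list alone. The median log2 difference was 1.48. Ube2c, a ubiquitin-conjugating enzyme of mitosis, rose 9.15-fold, cyclin B1, Ccnb1, rose by 2.56 ± 0.33 (SE) on the log2 scale, and Rrm2, a subunit of ribonucleotide reductase, rose by 2.92 ± 0.39. The list stood above the other probes by camera (adjusted p = 1.86e-05), a call lost with an estimated correlation (adjusted p = 0.422, the highest over alternatives that began at 1.21e-09). In sample medians of this list, normoxic sample 13 (8.14) lay among the hypoxic samples (7.91 to 8.60) and the other normoxic samples lay at 6.16 to 6.29. Markers of erythroid cells and of macrophages were higher in the same hypoxic samples. Of 7 erythroid genes, 5 rose and 7 did so adjusted over the list alone (median 2.09). Ahsp, which stabilises alpha globin, was at 3.52 ± 0.44 (SE) and the anion exchanger Slc4a1 at 2.09 ± 0.37. The erythroid median of normoxic sample 24 (8.75) came close to those of the hypoxic samples (9.04 to 9.94). Of 8 macrophage genes, 5 rose and 8 did so adjusted over the list alone (median 1.48), with Cd68 at 1.68 ± 0.23 (SE), Lyve1 at 2.17 ± 0.47 and Itgam at 1.60 ± 0.37. Camera called the erythroid list (adjusted p = 0.0364) and the macrophage list (0.0479), in neither case with an estimated correlation (adjusted p = 0.422 for each, the highest over alternatives that began at 0.00226 and 0.0260). The erythroid call also ended without normoxic sample 13 (adjusted p = 0.0618) or hypoxic sample 7 (0.0521). The macrophage call ended without normoxic sample 13 (0.0816), hypoxic sample 4 (0.0643) or hypoxic sample 5 (0.0798), or without hypoxic samples 4 and 5 together (0.212). Both lists ended without dim probes (0.162). The call of Itgam ended without normoxic samples 22 or 24 (log2 difference 1.45 and 1.41), with arrays centred (1.23, adjusted p = 0.0685) and without hypoxic samples 4 and 5, where the difference was 1.05 (adjusted p over all alternatives 0.00254 to 0.124).

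Tnni1 and 4 imprinted growth genes were higher in hypoxia at P8, and some genes of the adult cardiomyocyte and ion channel lists were lower. Tnni1, the troponin I isoform of the fetal heart, rose 12.7-fold, from 12.05 ± 1.73 (SD, n = 4) to 15.71 ± 0.79 (SD, n = 5), with a limma adjusted p of 0.00107. It was the only one of 6 fetal isoform genes to pass (1 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.691). Myh7, the slow myosin heavy chain, differed by 0.78 ± 0.38 (SE) and the natriuretic peptide Nppb by 0.75 ± 0.63, neither past the test and both unsteady over samples left out (0.34 to 1.12 for Myh7). Of 6 imprinted growth genes, 4 rose and 6 did so adjusted over the list alone (median 1.72), with Grb10 at 1.77 ± 0.28 (SE), Peg3 at 2.11 ± 0.36 and Plagl1 at 1.96 ± 0.51. Limma's fry called that list higher (adjusted p = 5.67e-04). Camera did not call it (adjusted p = 0.0534). It did with quantile normalization (0.0402), with arrays centred (0.0349), without normoxic sample 13 (0.0352), hypoxic samples 4 (0.0386) or 5 (0.0424) or both (0.0262), or hypoxic P30 sample 4 (0.0475), over a range of 0.0262 to 0.434. Of 3 adult cardiomyocyte genes, 2 fell, also adjusted over the list alone (median -1.55), among them the sarcomeric mitochondrial creatine kinase Ckmt2 at -2.08 ± 0.37 (SE). Of 9 ion channel and connexin genes, 4 fell and 1 rose, or 4 and 2 adjusted over the list alone (median -0.41). Kcnd2, a channel of the transient outward potassium current, was at -2.58 ± 0.48 (SE), its auxiliary subunit Kcnip2 at -1.39 ± 0.33 and connexin 43, Gja1, at -1.37 ± 0.34. Camera called both lists (adjusted p = 0.0480 for each), but not with an estimated correlation (adjusted p = 0.288 for the cardiomyocyte list and 0.396 for the channel list, the highest over alternatives that began at 0.0255 and 0.0377). Of these falling genes, Ckmt2 rose with age in normoxia (log2 difference 2.45 ± 0.39, SE), Gja1 fell (-2.01 ± 0.36), and Kcnd2 and Kcnip2 did not pass. The falls named here are thus only in part of genes gained with age.

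Some of these calls depended on single samples. Tnni1, Grb10, Peg3, Ckmt2 and Kcnd2 kept theirs under every alternative (adjusted p of at most 0.0302). The cardiomyocyte list ended without normoxic samples 22 or 23, hypoxic samples 6, 7 or 8, or hypoxic P30 sample 1 (adjusted p = 0.0505 to 0.0557), and with arrays centred (0.0800). The channel list ended without normoxic samples 13, 23 or 24, hypoxic samples 6, 7 or 8, or hypoxic P30 sample 1 (adjusted p = 0.0505 to 0.0617), with arrays centred (0.0744), without dim probes (0.0506) and without hypoxic samples 4 and 5 (0.0558). Among genes, Kcnip2 was lost without normoxic samples 22, 23 or 24 (adjusted p up to 0.0649), Gja1 without normoxic samples 13, 22 or 23 or hypoxic sample 6 (up to 0.0727), and Plagl1 without normoxic samples 22, 23 or 24 or hypoxic samples 6, 7 or 8 (up to 0.138) and with either rescaling of the arrays (0.0676 and 0.0751). Over all alternatives the adjusted p ran from 0.00273 to 0.106 for Kcnip2, from 0.00504 to 0.0727 for Gja1 and from 0.00631 to 0.138 for Plagl1. Over samples left out, their log2 differences stayed at -1.66 to -1.25, -1.46 to -1.21 and 1.58 to 2.22.

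**Figure D1:**
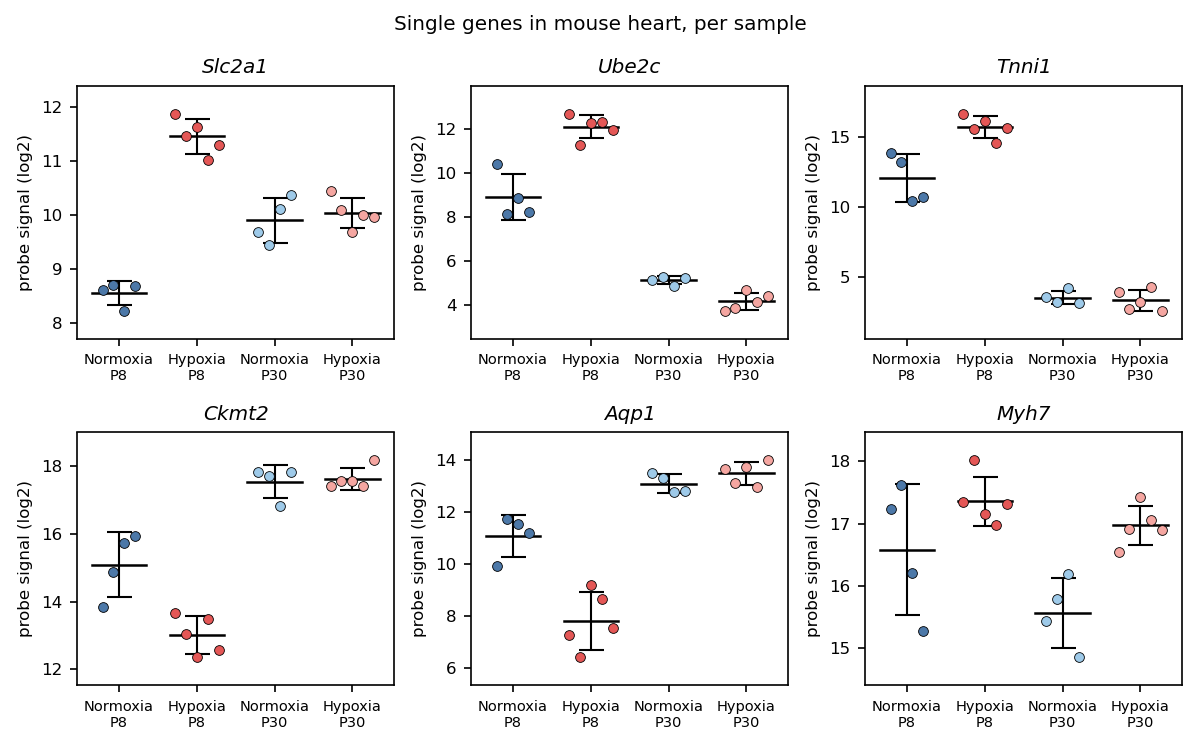
Log2 signal of Slc2a1, Ube2c, Tnni1, Ckmt2, Aqp1 and Myh7 in each sample of the 4 groups, with points for samples, a line for the group mean and a bar for its SD. Slc2a1 lay at 11.46 in hypoxia and 8.55 in normoxia at P8, but at 10.04 and 9.90 at P30.

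Transcripts induced by interferon had the largest rises at P8. Tgtp2, an interferon-induced GTPase, rose by 9.10 on the log2 scale, from 3.94 ± 1.21 (SD, n = 4) to 13.04 ± 4.43 (SD, n = 5), with a limma adjusted p of 0.00134. Its normoxic signal is dim and the size of the rise is uncertain, at 7.67 to 10.29 over samples left out and at 6.15 in the lowest alternative. The GTPases Iigp1 (log2 difference 6.79 ± 1.64, SE), Irgm1 (6.21 ± 1.36) and Gbp2 (6.14 ± 1.34), the transcription factor Irf7 (5.81 ± 1.33) and Ifi44 (5.60 ± 1.03) followed. Normoxic means of Irf7 (3.00), Ifi44 (4.32), Gbp2 (4.36) and Iigp1 (5.74) were under the limit for dim probes too (6.03), so the sizes and order of these rises are uncertain. A list of interferon-induced genes was drawn up only after these values had been seen. Of that list, 29 of its 29 genes with values rose, with a median of 4.44, and all 29 passed adjusted over the list alone. Camera gave an adjusted p of 1.13e-06, and 0.255 with an estimated correlation. The hypoxic samples differed widely in these genes. Sample medians were 12.78 and 13.14 in samples 4 and 5, 9.84 in sample 8, 7.50 in sample 6 and 7.14 in sample 7, and 5.14 to 6.13 in normoxic samples. Macrophage marker means were also highest in samples 4 (7.74) and 5 (7.62), against 6.53 to 6.85 in the other hypoxic and 5.14 to 5.91 in the normoxic samples. Neutrophil marker means went the same way, at 6.14 and 6.86 in samples 4 and 5, 4.85 to 5.29 in the other hypoxic and 3.58 to 4.48 in the normoxic samples. Without samples 4 and 5 the median was 2.63 and 17 of the 29 genes passed. Irf7 (3.14, adjusted p = 0.0510) and Iigp1 (3.42, 0.0585) did not pass then. Iigp1 was also lost without normoxic samples 22, 23 or 24 or hypoxic sample 4 alone (adjusted p = 0.0512 to 0.0625). Over all alternatives the adjusted p ran from 0.00420 to 0.107 for Iigp1 and from 0.00188 to 0.0919 for Irf7. With only the 2 groups compared in the fit, Irgm1 (adjusted p = 0.0833) and Gbp2 (0.0925) did not pass either, over alternatives that began at 0.00168 and 0.00234. At P30 all 29 interferon-induced genes lay lower in hypoxia (median -0.77), and limma called 0 of them, with 1, Lgals3bp, at an unadjusted p under 0.05 (camera adjusted p = 0.137).

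The largest falls at P8 were those of Egr1, an immediate early transcription factor, at a log2 difference of -3.58 ± 0.88 (SE), the water channel Aqp1 at -3.28 ± 0.45, Kcnd2, Plekhh1 at -2.48 ± 0.42, the apelin receptor Aplnr at -2.35 ± 0.53 and neprilysin, Mme, at -2.27 ± 0.45. Of 6 fibroblast and mural markers 2 fell, or 3 adjusted over the list alone (median -0.64). Decorin, Dcn, was at -1.82 ± 0.21 (SE). Camera called this list (adjusted p = 0.0364), but not without hypoxic samples 4 and 5 (0.0603) or with an estimated correlation (adjusted p = 0.332, the highest over alternatives that began at 0.00999). Of 13 extracellular matrix genes 3 rose and 2 fell, or 6 and 6 adjusted over the list alone. Tnc, the glycoprotein tenascin C, was at 1.64 ± 0.37 (SE), Col15a1 at -1.99 ± 0.30 and the proteoglycan Lum at -2.01 ± 0.36. Of 7 calcium handling genes 3 fell and 2 rose, or 3 and 4 adjusted over the list alone. The reticulum protein Hrc was at -2.03 ± 0.29 (SE), the sodium-calcium exchanger Slc8a1 at 1.29 ± 0.26 and sarcalumenin, Srl, at 1.11 ± 0.20. Of 5 endothelial markers 2 rose and 1 fell, or 3 and 1 adjusted over the list alone, with Eng at 1.61 ± 0.25 (SE) and Flt1, a receptor of VEGF, at 1.44 ± 0.29. Of 4 neutrophil markers 3 rose and 4 did so adjusted over the list alone, with S100a8 at 2.19 ± 0.38 (SE), Ngp at 1.96 ± 0.49 and Lcn2 at 1.67 ± 0.44. Of 3 stress genes Myc rose (2.19 ± 0.39, SE) and Egr1 fell, also adjusted over the list alone. Limma's fry called the neutrophil (adjusted p = 5.67e-04) and endothelial lists (0.0304) higher. Camera called none of these 5 lists (adjusted p = 0.269 for matrix, 0.622 for calcium handling, 0.691 for endothelial and stress genes and 0.141 for neutrophil markers). It pointed down for the matrix, calcium handling and fetal isoform lists although their medians were 0.03, 0.84 and 0.25.

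Lists with fewer than 3 measured genes were not tested as lists. Of 2 adrenergic genes none passed, and 1 rose and 1 fell adjusted over the list alone. Rgs4, a regulator of G protein signalling, was at a log2 difference of -0.88 ± 0.33 (SE). Of 2 lymphocyte genes 1 fell, or 2 adjusted over the list alone, with the recombinase gene Rag2 at -0.86 ± 0.23 (SE). The adipose marker Cidea was at 0.59 ± 0.28, 0 passing over all genes and 1 adjusted over the list alone. No atrial, skeletal muscle or lung marker had a named value per sample. Leaving out single samples ended the calls of Egr1 (normoxic 22, 23 or 24, adjusted p up to 0.109), Aplnr (normoxic 24, 0.0501), Tnc (normoxic 24, 0.0610), Ngp (normoxic 13 or 22 or hypoxic 4, up to 0.0955), Lcn2 (normoxic 13, 22 or 23 or hypoxic 4, 5, 6 or 8, up to 0.123) and Rag2 (normoxic 22, 23 or 24 or hypoxic 4, 5, 7 or 8, up to 0.170). Over all alternatives the highest adjusted p was 0.109 for Egr1, 0.0679 for Aplnr, 0.0785 for Tnc, 0.163 for Ngp, 0.186 for Lcn2 and 0.212 for Rag2. Without hypoxic samples 4 and 5 together, Ngp was at 1.07 (adjusted p = 0.163), Lcn2 at 1.30 (0.186), Aplnr at -1.48 (0.0679), Rag2 at -0.71 (0.212) and Egr1 at -3.59 (0.0573), and none of them passed. Rgs4 passed with arrays quantile normalized or centred (0.0366 in both).

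**Figure D2:**
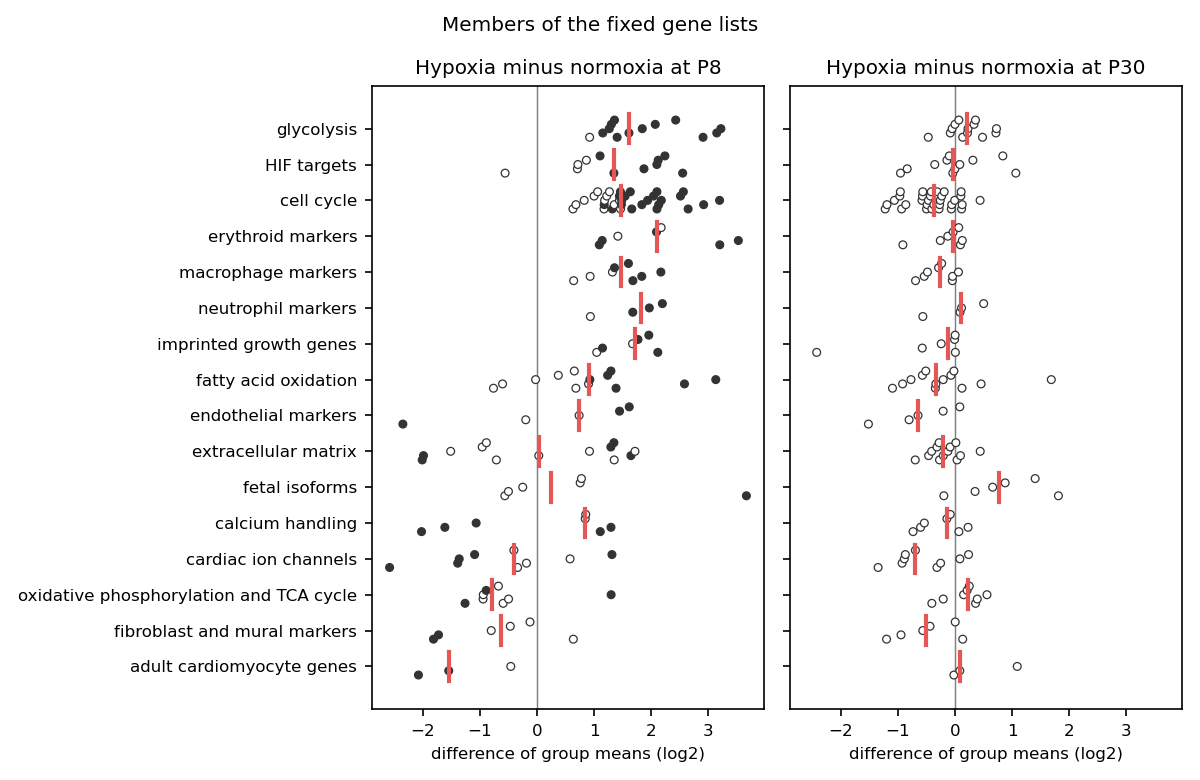
Log2 difference between hypoxia and normoxia of each measured gene of 16 gene lists at P8 and at P30, with a dot per gene, filled where its adjusted p passed, and a red bar at the list median. At P8 the medians of the glycolysis and cell cycle lists stood at 1.61 and 1.48, and at P30 no gene passed.

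Over all probes with values, limma called 976 at P8, 714 higher and 262 lower in hypoxia. In 1190 probes (25.3%) the samples of both groups did not overlap. Chance gives 1.59% of unselected probes, and the selection of these probes raises that share by itself. The median of all probes was 0.18, and sample medians over these probes were higher in hypoxic P8 samples (7.87 to 8.07) than in the others (7.38 to 7.69). Rescaling over these selected probes, not over the array, moved that median to -0.08 with quantile normalization and to -0.19 with arrays centred, and turned the balance. The calls were 339 higher and 541 lower of 880, and 322 higher and 830 lower of 1152. The share of higher calls was thus 73.2%, 38.5% or 28.0%, while no called gene or list named above changed its direction. Since this rescaling makes the sample medians of a selected set equal, it does not show whether the balance comes from normalization. Leaving out normoxic sample 22 or 24 gave 632 and 566 calls. In simulated data of this design with 100 changes of each size, 32% of changes of 1 log2 unit and 86% of changes of 2 units were recovered at P8.

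The authors' deposited table for P8 lists 4351 probes with an unadjusted p of up to 0.05, 2240 higher and 2111 lower in hypoxia. Of these, 760 have a q-value under 0.05, 497 higher and 263 lower. Only 2312 of the 4351 probes had values per sample here, so limma's counts cover a part of that table. In the authors' deposited table the largest rises were those of Tgtp2 (731.6-fold), Iigp1 (112.6), the GTPase Igtp (96.58), Ifi44 (95.62) and Gbp2 (72.3), and the largest falls those of Egr1 (-13.65), Aqp1 (-12.98), Kcnd2 (-8.02), Ecm2 (-6.02) and the phosphatase Dusp1 (-5.25). Of the 39 cell cycle genes, the authors' deposited table lists 33, all higher, which an exact binomial test put above the 19.6% of the array that is listed (adjusted p = 5.26e-17). The test takes genes as independent, whereas camera's estimated correlation of this list was 0.439, so such p-values are too low. By the same exact test, the authors' deposited table held more than that share of glycolysis genes (15 of 22, all higher, adjusted p = 5.20e-06), macrophage markers (12 of 15, all higher, 5.20e-06), oxidative phosphorylation genes (16 of 34, 12 of them lower, 0.00119), fatty acid oxidation genes (13 of 30, 11 higher, 0.00941), HIF targets (12 of 27, 11 higher, 0.00941), matrix genes (13 of 32, 7 higher, 0.0146) and imprinted growth genes (6 of 12, all higher, 0.0458). Of atrial, skeletal muscle and lung markers it lists 0 of 11, 0 of 12 and 0 of 8, counts too low for this test of excess to speak on. The exact test did not pass for the other lists in the authors' deposited table: erythroid markers (7 of 19, all higher, adjusted p = 0.133), fibroblast markers (4 of 14, 3 lower, 0.416), adult cardiomyocyte genes (5 of 20, 3 lower, 0.483), ion channels (7 of 33, 5 lower, 0.590), fetal isoforms (4 of 12, 2 lower, 0.298), endothelial markers (7 of 18, 6 higher, 0.110), stress genes (6 of 16, 4 lower, 0.150), calcium handling (7 of 22, 4 higher, 0.227), neutrophil (4 of 11, all higher) and lymphocyte markers (5 of 15, all lower), adrenergic genes (5 of 21, 3 higher, 0.514) and adipose markers (2 of 10, 1 higher, 0.723). The authors' deposited tables of enriched Gene Ontology terms, whose comparison is not stated, hold 319 biological processes, led by small molecule metabolic process (enrichment 2.1, p = 4.02e-10), monocarboxylic acid biosynthetic process (9.11) and ADP metabolic process (17.47). Cytoplasmic part led 46 cellular components and protein binding led 42 molecular functions in the authors' deposited tables.

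At P30, the fetal isoform genes with values were higher as a group in hypoxic hearts, and no single gene passed the test. Of 6 fetal isoform genes, 5 were higher, with a median log2 difference of 0.77. Nppb differed by 1.81 ± 0.63 (SE), Myh7 by 1.41 ± 0.38, from 15.57 ± 0.57 (SD, n = 4) to 16.97 ± 0.31 (SD, n = 5), the muscle genes Xirp2 and Smpx by 0.88 ± 0.37 and 0.66 ± 0.21, and Tnni1 by -0.19 ± 0.59. With age in normoxia Nppb, Tnnt1 and Tnni1 of this list fell, Xirp2 rose and Myh7 and Smpx did not pass, so the list is only in part one of genes lost with age. Camera placed the list above the other probes (adjusted p = 0.00325, and 0.0314 with an estimated correlation, over alternatives of 8.22e-04 to 0.0314). Only 6 of the 12 members could be tested. Genes were named only through the authors' lists of differing probes, which favours members that differ at P30 and so can favour this call. In the authors' deposited table for P30, 4 of the 12 list members appear, all higher, which did not pass the exact binomial test (adjusted p = 0.180), and no other list passed it at P30. By limma, 0 of the list genes passed over all genes tested and 4 did adjusted over the list alone. It was the only one of 17 lists that camera called. Leaving out normoxic P8 sample 13 (2 lists), normoxic P30 sample 2 (2 lists) or normoxic P30 sample 5 (3 lists) added the cell cycle list, the ion channel list, and the glycolysis and cell cycle lists. Those 3 lists had an adjusted p of 0.0977 with all samples, over alternatives of 0.0107 to 0.751 for ion channels, 0.0189 to 0.791 for glycolysis and 0.0194 to 0.791 for cell cycle genes. Their medians were -0.69, 0.22 and -0.37.

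No member of the other lists passed over all genes tested at P30. Adjusted over the list alone, 4 of 9 ion channel genes fell, and of 3 stress genes 1 rose and 2 fell. In the other lists at most 1 gene passed per direction. Limma's fry called the ion channel list lower (adjusted p = 0.0420), which camera did not. In each of 10 lists the member with the largest statistic was named: Scn4b, a sodium channel subunit (-1.35 ± 0.33, SE), the carnitine transferase Cpt2 (-1.09 ± 0.26), the HIF target Fam162a (1.07 ± 0.26), the imprinted gene Mest (-2.42 ± 0.70), the tight junction gene Cldn5 (-1.52 ± 0.46), Sparc (-0.69 ± 0.20), Myc (-1.24 ± 0.39), the spindle gene Tpx2 (-1.06 ± 0.35), the sarcomere gene Myom2 (1.09 ± 0.38) and Pfkp (0.73 ± 0.27). The same members of the remaining lists, Pi16 (-0.94 ± 0.39), Camk2b (-0.73 ± 0.35), Fh1 (0.56 ± 0.27), C1qa (-0.69 ± 0.37), Alas2 (-0.91 ± 0.75), S100a8 (0.50 ± 0.38), Rgs4 (-0.16 ± 0.33), Rag2 (0.09 ± 0.23) and Cidea (-0.07 ± 0.28), had smaller statistics, and Slc2a1 differed by 0.14 ± 0.23. Leaving out single samples moved Alas2 to as little as -0.24, Myc to -0.75, Camk2b to -0.44 and Pi16 to -0.61. Limma called 0 probes, against 656 with an unadjusted p under 0.05, 234 higher and 422 lower. The lowest adjusted p was 0.112. Leaving out normoxic P30 sample 2 gave 2 calls and leaving out normoxic P30 sample 5 gave 3. In simulated data of this design with 100 changes of each size, 22% of changes of 1 log2 unit and 91% of changes of 2 units were recovered at P30. Recovery depends on how many probes change, and with 0 calls here it can be lower. The authors' deposited table for P30 lists 1524 probes, 821 higher and 703 lower, of which 1, Wsb2 (2.12-fold, q = 0.0185), has a q-value under 0.05. The listed probes are 6.86% of the array, at an unadjusted p of up to 0.05. Only 635 of them had values per sample here, so limma's counts cover a part of that table. The largest rises in the authors' deposited table were those of Nr4a3 (14.14-fold), Nmrk2 (4.86), Rcan1 (4.69), Nppb (4.36) and Tnfrsf12a (3.55), and the largest falls those of Mest (-8.76), Egr1 (-7.09), Lgi1 (-4.35), Bdh1 (-4.16) and Man2a2 (-3.72).

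The effect of hypoxia itself differed between the ages. Slc2a1 was higher by 2.91 at P8 and by 0.14 at P30, a difference of -2.77 ± 0.33 (SE). Csrp1, a muscle LIM protein, went from 3.73 to -1.18 (-4.91 ± 0.55) and Lgals3bp, a galectin ligand, from 4.29 to -1.07 (-5.36 ± 0.65). Next were the acyl-CoA thioesterase Acot1 from 2.46 to -0.88 (-3.34 ± 0.39), Rasl11b, a small GTPase, from 2.82 to -0.39 (-3.20 ± 0.35) and the inositol phosphatase Impa2 from 1.91 to -0.61 (-2.52 ± 0.30). Their limma adjusted p ran from 2.20e-04 to 3.09e-04, over alternatives of 6.08e-06 to 0.00412. As a group, cell cycle genes differed (11 of 33 lower in the effect at P30, 31 adjusted over the list alone, median -1.99, camera adjusted p = 1.15e-05), as did glycolysis genes (8 of 13, 12 adjusted over the list alone, median -1.61, 6.78e-04). The difference was positive for oxidative phosphorylation genes (1 of 8, or 6 against 1 adjusted over the list alone, median 1.08, 0.00712) and adult cardiomyocyte genes (0 of 3 by limma, 3 adjusted over the list alone, median 1.55, 0.0363). Erythroid and macrophage markers moved along with the cell cycle genes (medians -1.99 and -1.84, 1 lower in each over all genes, 7 of 7 and 7 of 8 adjusted over the list alone), though camera did not call them (adjusted p = 0.0670 and 0.0561). With an estimated correlation none of the 4 called lists was called (adjusted p = 0.455, 0.232, 0.347 and 0.232). In all, 243 probes passed the test of the difference, 39 higher and 204 lower (16.0% higher). Of all probes, 1950 had an unadjusted p under 0.05. With quantile normalization 193 of 282 were higher (68.4%), and with arrays centred 476 of 570 (83.5%), as the median of all probes moved from -0.31 to 0.09 and 0.22. Leaving out normoxic P8 sample 13, hypoxic P8 sample 5 or normoxic P30 sample 3 gave 375, 376 and 139 calls.

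Between P8 and P30, transcripts of imprinted growth genes, matrix genes and dividing cells fell in normoxic hearts. Tnni1 fell by 8.53 ± 0.62 (SE) on the log2 scale, Igf2, the fetal growth factor, fell by 4.46 ± 0.36, Thbs1, the matrix protein thrombospondin 1, fell by 4.49 ± 0.45, and of the imprinted genes Plagl1 fell by 4.11 ± 0.53 and Mest fell by 4.01 ± 0.74. The metallothionein Mt2 rose by 6.06 ± 1.02, xanthine dehydrogenase, Xdh, by 5.77 ± 1.09, Tmtc1 by 4.59 ± 0.51, Rpl3l, a ribosomal protein of striated muscle, by 4.58 ± 0.39 and Timp4, a metalloproteinase inhibitor, by 4.50 ± 0.48, all with a limma adjusted p of at most 0.00191. Of 33 cell cycle genes 21 fell (32 adjusted over the list alone, median -1.40), of 13 matrix genes 8 fell (10, median -1.89) and of 6 imprinted growth genes 5 fell (6, median -3.14), while of 8 macrophage markers 7 rose (8, median 1.97). Of 6 fetal isoform genes 3 fell and 1 rose (4 and 1 adjusted over the list alone), without a call of the list (camera adjusted p = 0.127). Of the fixed lists, camera called the 4 former and no other (adjusted p = 5.86e-09, 6.23e-05, 1.72e-04 and 2.35e-05), none of them with an estimated correlation (adjusted p = 0.232, 0.201, 0.213 and 0.201). It also called the interferon-induced list drawn up later (27 of 29 higher at P30, median 1.53, adjusted p = 0.00925, and 0.513 with an estimated correlation). Limma called 0 of its genes, also adjusted over the list alone, with 7 at an unadjusted p under 0.05. Limma called 1627 probes, 859 higher and 768 lower at P30, and 1079 without normoxic P30 sample 3. The median of all probes was -0.11. For both comparisons between ages, lists and background held only genes named through the authors' hypoxia comparisons. The 2031 probes without a name were left out, so the list calls do not survey all change with age.

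In hypoxic hearts the same interval brought a fall of all 33 cell cycle genes, also adjusted over the list alone, with a median of -3.39. Ube2c fell by 7.91 ± 0.35 (SE) on the log2 scale and cyclin A2, Ccna2, fell by 6.82 ± 0.46, Tnni1 fell by 12.39 ± 0.56, Mest fell by 8.10 ± 0.66 and the adhesion molecule Ncam1 fell by 7.37 ± 0.65. Rpl3l rose by 6.44 ± 0.35, Aqp1 by 5.68 ± 0.43, Art1, an ADP-ribosyltransferase of muscle, by 4.74 ± 0.45, Ckmt2 by 4.61 ± 0.35 and the clock-controlled transcription factor Dbp by 4.27 ± 0.55. All 6 imprinted growth genes fell (6 adjusted over the list alone, median -5.06), and 11 of 13 glycolysis genes fell (13 adjusted over the list alone, median -1.29). All 7 erythroid markers fell (7 adjusted over the list alone, median -2.73), 7 of 8 oxidative phosphorylation genes rose (7 adjusted over the list alone, median 1.24) and 2 of 3 adult cardiomyocyte genes rose (2 adjusted over the list alone, median 2.60). Camera called these 6 lists (adjusted p = 1.39e-10 for cell cycle, 0.00184 for imprinted, 0.00637 for glycolysis, 0.0173 for erythroid, 0.00321 for oxidative phosphorylation and 0.0407 for cardiomyocyte genes). None held with an estimated correlation (adjusted p = 0.281 for 5 of them and 0.368 for erythroid markers). Limma called 3304 probes, 1237 higher and 2067 lower at P30, or 37.4% higher. That share was 55.5% of 2887 with quantile normalization and 61.4% of 2963 with arrays centred, as the median of all probes moved from -0.50 to -0.16 and -0.03.

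Across probes, which are not independent replicates, the effect of hypoxia at P8 had almost no linear relation to the change with age in normoxia (Pearson r = 0.00283, Spearman rho = -0.0659). Unchanged groups simulated against the same normoxic samples gave r = 0.155, and with those samples split so that none was shared, r was -0.0507 on average over 6 splits (-0.147 to 0.0479). At P30 the relation was r = -0.178 (rho = -0.159), against -0.153 for unchanged groups and -0.0457 with split samples (-0.191 to 0.104). The effects at P8 and P30, which share no sample, had r = -0.119 (rho = -0.103, jackknife SE of r 0.0518), against 0.00197 (-0.0522 to 0.0585) for unchanged groups, a range from simulated probes that are independent and so too narrow. These were the 3 relations computed. Of the probes called in both comparisons, 77 rose in hypoxia at P8 and rose with age, where independent lists share 130.4, and 44 fell in both, where independent lists share 42.8. In the opposite directions, 89 rose in hypoxia and fell with age (116.6 for independent lists), and 31 fell in hypoxia and rose with age (47.8). Both comparisons hold the same normoxic P8 samples, which by itself favours equal directions, and the counts expected from that alone were not computed. The counts for independent lists are over the selected probes with values and would be lower over the array. Neither a shortfall nor an excess can therefore be read from them.

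**Figure D3:**
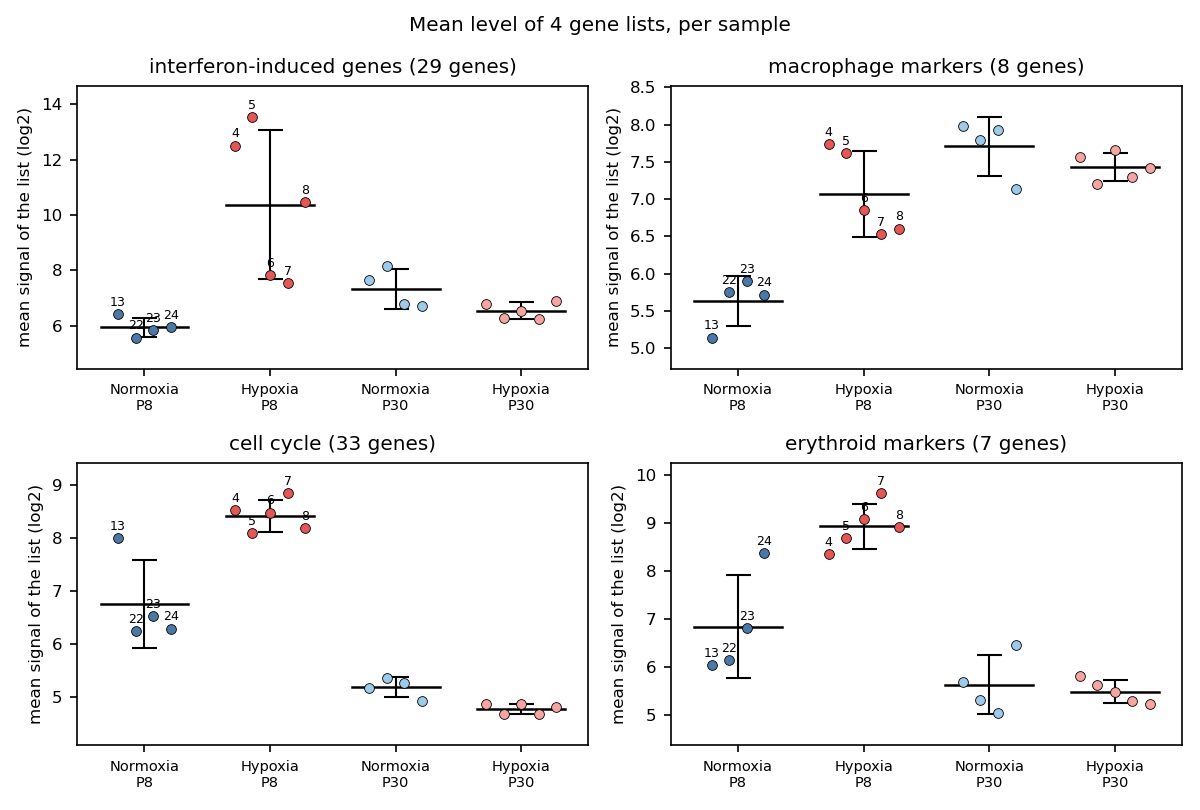
Mean log2 signal of the interferon-induced, macrophage, cell cycle and erythroid genes in each sample of the 4 groups, with a line for the group mean, a bar for its SD, and P8 samples labelled by number. The interferon-induced genes stood at 12.51 and 13.54 in hypoxic P8 samples 4 and 5, and at 7.53 to 10.47 in the other hypoxic P8 samples.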

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

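The splits of samples were planned before the data were examined, and all other tests of explanations in this part were chosen only after the result was seen.

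In 85 named genes, the highest or lowest sample of a group lay far from the rest by Dixon's ratio in 14 of 340 groups, where chance gives 5%. In normoxic P8 samples these were Tgtp2 in sample 13 (5.74, others 3.14 to 3.55), Irgm1 in sample 24 (5.63, others 6.78 to 6.90), Aplnr in sample 13 (9.47, others 10.71 to 10.89) and Itgam in sample 23 (5.07, others 3.23 to 3.50). In hypoxic P8 samples they were Eng (15.67, others 14.54 to 14.79) and Fam162a (11.24, others 12.20 to 12.57), both in sample 6. In normoxic P30 samples they were Ckmt2 (16.81, others 17.70 to 17.84) and Angptl4 (9.92, others 8.15 to 8.36) in sample 4, and Rrm2 (5.14, others 6.17 to 6.31) and Mt2 (7.78, others 14.14 to 14.78) in sample 5. In hypoxic P30 samples they were Ckmt2 in sample 5 (18.18, others 17.41 to 17.57), Myc (3.77, others 5.03 to 5.41) and Sparc (17.24, others 17.90 to 18.15) in sample 1, and Myom2 in sample 3 (14.19, others 15.61 to 15.81).

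The effect of hypoxia differed between the ages in 243 probes by the interaction test, and the genes with the largest statistics were Rasl11b (-3.20), Csrp1 (-4.91), Acot1 (-3.34), Slc2a1 (-2.77), Impa2 (-2.52) and Lgals3bp (-5.36).

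Other splits of the same samples into groups of the same sizes gave fewer calls than the real ones. At P8 only 1 of 100 drawn splits, the real one, reached its 976 calls, and the highest of the others gave 295. For the difference in effect 1 of 100 reached 243 (highest other 114), for age in normoxia 1 of 35 reached 1627 (highest other 3), and for age in hypoxia 1 of 100 reached 3304 (highest other 5). Since the probes had been selected with the real groups, which favours the real split, these shares do not settle whether chance is excluded. At P30 the real count was 0, which any split must reach (100 of 100 did, the highest other 2), so this test says nothing there.

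The interferon-induced genes were higher in hypoxia at P8 by a median of 4.44, with hypoxic samples from 7.14 to 13.14. Samples 4 and 5 alone do not account for all of it, since without them the median was 2.63 and 29 of 29 genes were still higher. Sample 8 (9.84) lay well above samples 6 (7.50) and 7 (7.14), so the remainder rests much on sample 8. The genes were chosen on values that included samples 4 and 5. They also move together (camera's estimated correlation 0.788), so 29 of 29 does not count separate results. With the macrophage marker mean as a covariate the median dropped to 0.756 (17.0% of its value), with 1 of 29 genes past the threshold where all 29 were before, 26 still higher and a median SE of 1.34 against 0.95, which meets what more macrophages in the hypoxic hearts would show, though the covariate is tied to the group and inflates the SE. A second criterion was added after that result. If markers follow cell number in proportion, more cells alone, each with unchanged expression, could raise a gene by no more than their markers. The median lay 2.27 above the rise of the strongest macrophage marker, Lyve1, and 27 of 29 genes exceeded it. Macrophage marker means in normoxic P8 samples (5.14 to 5.91) were under the limit for dim probes (6.03), where rises can be understated. This criterion therefore cannot exclude more macrophages alone. In the 4 normoxic P30 samples, macrophage marker means were 7.13 to 7.99, against 7.74 and 7.62 in hypoxic P8 samples 4 and 5. Interferon medians of those P30 samples were 5.89 to 7.16, against 12.78 and 13.14. If expression per macrophage is alike at both ages, these values argue against more macrophages alone in samples 4 and 5. In the other hypoxic P8 samples more macrophages alone stay open. Macrophages that came with induced genes, neutrophils, whose markers were highest in the same samples, an interferon response in other cells, an infection in some litters and hypoxia itself, the difference the design names, remain open too and were not tested.

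The cell cycle genes were higher in hypoxia at P8 by a median of 1.48, and erythroid precursors or macrophages that divide could bring such transcripts. With the erythroid marker mean as a covariate the median was 2.08, with 6 genes past the threshold in place of 21 and a median SE of 0.575 against 0.371. With the macrophage marker mean it was 2.10, also with 6 genes past the threshold. Neither covariate lowered the median and 33 of 33 genes stayed higher with each, but fewer passed with the larger SE of covariates that follow the group, so the explanations cannot be told apart from hypoxia by the rule set for this test. Which cells carry the transcripts was not measured, and an effect of hypoxia on dividing heart cells stays open as the biological explanation.

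Whether hypoxia moved hearts against the change with age was weighed with the samples that both comparisons share. At P8 the covariance of effects across probes was 0.00325, below the 0.0687 (0.0479 to 0.0887) of unchanged groups against the same normoxic samples, but its jackknife SE of 0.0732 is as wide as that gap. At P30 it was -0.0939, against -0.0677 (-0.0923 to -0.0446), with an SE of 0.0825, so the effect may come from the shared samples or from age and these cannot be told apart here. The simulated ranges treat probes as independent and are too narrow. A delay of maturation, the explanation the title names, therefore stays open at both ages in this measure.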

How the results depend on the processing

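The adjustment over the table alone and the settings without hypoxic P8 samples 4 and 5 were chosen after seeing the data, as were the checks of the numbers. Of 1977 refits of 106 gene results, 1880 kept direction and side of the threshold, 83 lost and 3 gained the call, and 11 reversed, none of them in a called gene. Of 812 refits of 34 list results, 765 kept their side of the threshold, 36 lost and 11 gained the call. Direction was compared only where a list was called with the main or the changed setting, and there none changed. Medians of lists never called did change sign, as for calcium handling at P8 (-1.07 to 0.915), fetal isoforms at P8 (-0.12 to 0.37), matrix genes at P8 (-0.34 to 0.20) and 6 lists at P30. For the following changes the cause was not tested unless stated. Dim probes left out gave 510 calls at P8 and 157 for the difference in effect, and 1 probe per gene gave 550 for age in normoxia and 1568 for age in hypoxia, where by construction fewer probes were tested. Only the groups compared gave 429 at P8 and 1053 for age in normoxia, with fewer samples. Adjusting over the table alone, with fewer tests, gave 1938 at P8, 4 at P30, 1191 for the difference and 2669 for age in normoxia. Array weights gave 5 at P30 and 608 for the difference, arrays centred 570 for the difference, and a fold of 2 with an unadjusted p 124 at P30 and 1414 for the difference. Without hypoxic P8 samples 4 and 5 the difference gave 478 and the relation at P8 an r of -0.0784. Camera with an estimated correlation called 0 lists at P8 (9 with the preset one), and 0 between ages in normoxia (4), in hypoxia (6) and for the difference (4). The numbers did not pair the samples: deviations of equal numbers at P30 correlated at -0.0772, -0.0109, 0.0743 and -0.168, and in hypoxia between ages at -0.211 and 0.182. A replicate block gave 0 calls at P30, as without it, and 1115 for age in hypoxia with numbers 4 and 5 alone. Leaving out each sample gave 566 to 978 calls at P8, 0 to 3 at P30, 139 to 376 for the difference, 1079 to 1621 for age in normoxia, 2982 to 3332 for age in hypoxia, and 1 to 3 lists at P30. Reversals were of Rag2 at P30 with quantile normalization (-0.0068) and the block (-0.005), and Cidea at P30 with quantile normalization (0.10) and arrays centred (0.089). Over samples left out, Nppb at P8 ran from -0.0473 to 1.24, and at P30 Rgs4 from -0.48 to 0.15, Rag2 from -0.005 to 0.19, Cidea from -0.20 to 0.085, Tnni1 from -0.43 to 0.0227 and Slc2a1 from -0.0187 to 0.29. A covariate of Y-linked genes, alone or with the block, was not run, since none of the 4 genes has a named value here. Signal over background was not analysed here.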

Other observations

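All tests in this part were chosen only after the result was seen.

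Genes that cells induce when amino acids run short or proteins misfold were higher in hypoxic hearts at P8. Of 14 measured genes of an amino acid response list, 10 rose, 13 passed upward and 1 downward adjusted over the list alone, and the median log2 difference was 1.32. They included the tryptophanyl-tRNA synthetase Wars (3.31 ± 0.50, SE), also known as an interferon-induced gene, the amino acid transporter Slc7a5 (2.86 ± 0.34), asparagine synthetase, Asns (2.65 ± 0.35), Psat1 of serine synthesis (2.39 ± 0.35) and the mitochondrial folate enzyme Mthfd2 (2.38 ± 0.40). Camera gave an adjusted p of 0.00252 over the 2 lists added, and 0.0848 with an estimated correlation. Limma called 0 of the 14 at P30, and 0 had an unadjusted p under 0.05, where the median was -0.05 and 5 of 14 were higher. The difference between the ages passed the test in the 5 named genes and in none of the other 9 (adjusted p = 0.00578 for Slc7a5, 0.0116 for Psat1, 0.0133 for Wars, 0.0138 for Asns and 0.0278 for Mthfd2). In the authors' deposited table for P8, 18 of the 25 list members appear, 17 of them higher (exact binomial test, adjusted p = 1.81e-07 over the fixed and added lists).

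A position on an axis of age, from 0 at the normoxic P8 mean to 1 at the normoxic P30 mean over the 1627 probes called between them, put hypoxic P30 hearts at 0.920 ± 0.0392 (SD, n = 5), below the 0.979 (0.961 to 0.996) of simulated unchanged groups. The hypothesis that they lag was tested by setting the axis on 2 normoxic samples per age and placing the samples left out. Over 36 such splits the hypoxic P30 samples differed from the left-out normoxic ones by -0.00259 (-0.0894 to 0.0905) and were lower in 18 of 36. The lower position may therefore come from the normoxic samples having set the axis, and no lag at P30 was shown. At P8 the hypoxic samples lay at 0.0162 ± 0.0528 (SD, n = 5). They differed from the left-out normoxic ones by -0.0703 (-0.208 to 0.0356) and were lower in 32 of 36 splits. These splits reuse the same samples and are not independent. The SD of single normoxic P8 samples on the axis of all 1627 probes was 0.0872, which is not the spread of that difference. Whether hypoxic hearts lag at P8 is therefore not decided here.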
